A study of Mus musculus with 3 samples.

How the data were processed

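Gene expression was measured with 1-colour oligonucleotide microarrays in mouse tail-tip fibroblasts taken through reprogramming with 4 factors (Oct4, Sox2, Klf4 and c-Myc) and collected on day 8. The labels give 3 groups with 1 array each: cells of young wild-type (WT) donors aged 2 months, of old WT donors aged 22 months, and of old donors aged 22 months that lack p16 (p16-/-). The study design mentions 2 independent experiments with different donors, and 1 array per group was analysed here.

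The deposited scanner files hold linear spot intensities made with Agilent Feature Extraction 11.5.1.1 from Cy3-stained RNA, per the file headers. The intensity used was the processed signal, which per the file headers is background-subtracted and spatially detrended and was not normalized between arrays. The deposited series value table holds the same linear intensities without scaling, centring or log transformation. Its values equalled the processed signal within a relative tolerance of 0.0001 for 39030 of 39030 probes spotted once, on each array. Its column medians were 137 for young WT, 135 for old WT and 132 for old p16-/-. The 3 arrays sat on 1 slide and were read in 1 scan, so slide and scan do not separate the groups.

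Control spots (1377) were left out, as were spots that Feature Extraction had marked as non-uniform or as population outliers (246, 246 and 267 spots on the young WT, old WT and old p16-/- arrays). No spot was saturated. The log2 processed signal was averaged over the spots of a probe, and each array's 75th percentile was subtracted. Probes carry a sequence accession and no gene name. The accession, without its version, was matched to a RefSeq gene table of the GRCm38.p6 assembly, which named 27508 of 39429 probes and left 11921 unnamed. The probes were designed on another build (mm9, per the file headers), so the gene table was used only for names, chromosomes and neighbours, and no coordinates are given. A gene was represented by its brightest probe (highest mean over the 3 arrays), which gave 20825 genes, of which 12887 were well above background on all 3 arrays.

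A comparison counted a gene if Feature Extraction called it well above background on at least 1 of the 2 arrays, by any of its probes. For 15, 14 and 16 genes on the young WT, old WT and old p16-/- arrays this was a probe other than the brightest, whose ratio was then taken as measured although its own level can lie under the limit given next. Where only 1 of the 2 was above background, the ratio is a bound: the bright array's level against the higher of the dim probe's own level and the lowest level among probes above background on that array. A bound under 1-fold was entered as no difference. Genes were described by size, at least 2-fold (a log2 ratio of 1 in either direction). With 1 array per group there is no spread between replicates, so no test was run, no p-value can be given, and the number of arrays limits the precision of every value. For 27 gene lists (81 list-by-comparison values, of which 79 had the 3 counted members needed for a median), the median log2 ratio was placed among the medians of 10000 random lists of equal size matched on decile of mean expression. A list in the outer 5% is said to stand apart, as a description of these arrays. Of 632 list entries, 625 were matched to the array; Mx1, Mx2, Gsta1, Hspa1b, Cd68, Bglap and Polr2a were not.

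The genes named in the text follow a rule fixed before the data were examined. It takes the 12 highest and 12 lowest ratios of each comparison among genes above background on both arrays with an ordinary symbol, the 5 largest bounds in each direction, Cdkn2a and the 4 factors, and up to 4 members per list that were at least 2-fold apart, with up to 4 that were not where a list is described. For genes that lay in opposite directions across the comparisons, it takes 10 per direction. A further set was chosen after the data were seen: the 12 highest and 12 lowest ratios of old WT over young WT among genes with a processed signal of at least 1000 on the brighter array.

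Measurement noise was read from 399 probes spotted 10 times. The median SD of log2 signal over replicate spots above background was 0.0549, 0.0571 and 0.0546 on the young WT, old WT and old p16-/- arrays. Replicate spots were also read singly, with those marked as outliers included. Among spots of probes with a median signal of 1000 or more, 0 of 1750, 0 of 1700 and 0 of 1720 lay at least 2-fold from their probe's median. Among spots of dim probes, 66 of 1390 (4.75%), 81 of 1290 (6.28%) and 69 of 1400 (4.93%) were called well above background, with signals of up to 694, 794 and 870. Most genes rest on a probe spotted once, for which such spots cannot be recognised. Counts are therefore given a second way, for genes whose brighter array has a signal of at least 1000, a threshold chosen after the data were seen.

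Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, median centring, cyclic loess, a background filter on both arrays or none, the mean of all probes of a gene, outlier spots kept, the deposited series values, a 3-fold size, unmatched random lists and the mean of list members. Normexp was run on median spot and background intensities, because the deposited files hold no mean spot intensity. Removal of genes on the X and Y chromosomes, the background call of the brightest probe in place of any probe, and the threshold of 1000 were added after the data were seen. The steps were tested on data simulated from the young WT array with 20825 genes and noise of the size seen between replicate spots. All 150 genes changed by at least 2.83-fold and 0 of 50 genes changed by 1.41-fold were called at 2-fold, as were 0 of 13392 unchanged genes. Of 200 random lists 8 stood apart, and of 20 lists shifted by 0.50 on the log2 scale 20 did. This simulation holds no single-spot artefacts, so it does not measure their effect. Its noise is independent between probes and its unshifted lists are random, so it does not show how often lists of genes that vary together stand apart. Its changed genes and shifted lists were drawn from brighter probes well above background on young WT. As its noise is far smaller than the 2-fold cut, the calls of single genes were nearly fixed in advance. They check the steps and do not show how often separate cultures differ by 2-fold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.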

Results

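Tail-tip fibroblasts of young WT, old WT and old p16-/- mice were profiled on day 8 after introduction of 4 reprogramming factors, with 1 array per group. The series compares reprogramming intermediates of old and young cells and of old cells with and without p16, a cyclin-dependent kinase inhibitor encoded by Cdkn2a. Of 43020 spots, 24682 (57.4%) were well above background on the young WT array, 26504 (61.6%) on the old WT array and 25110 (58.4%) on the old p16-/- array. The 75th percentile of processed signal was 2338, 2255 and 2243. Ratios are given as log2, and no difference has a replicate check.

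Cdkn2a was well above background on all 3 arrays, with a processed signal of 62705 on young WT, 65464 on old WT and 28065 on old p16-/-. Its log2 ratio was 0.12 for old WT over young WT and -1.23 for old p16-/- over old WT. A second probe gave 0.12 and -1.38. Cdkn2a encodes both p16 and the tumour suppressor Arf from partly shared exons, and neither probe is known to lie in the deleted part, so these signals do not check the genotype. Cdkn2b, the neighbouring gene for the inhibitor p15, was also lower on the p16-/- array than on old WT (-1.27).

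Among the reprogramming factors, Klf4 differed little, at 0.31 for old WT over young WT and -0.35 for old p16-/- over old WT. Myc was at 0.02 and -1.03. Pou5f1, which encodes Oct4, was not well above background on any array. Sox2 was above background on the p16-/- array, at a signal of 73, a range in which single spots of dim probes were also called. Whether these probes detect the introduced factors is not given in the sources used here.

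Sex-linked genes differed between arrays. The Y-linked genes Eif2s3y and Ddx3y had signals of 6819 and 3949 on the young WT array and were not well above background on either old array, with bounds of -7.52 and -6.73 for old WT over young WT. Uty was lower by a bound of -1.95. Xist, the transcript of the inactive X chromosome, was not well above background on young WT and had signals of 1548 and 1387 on old WT and old p16-/-, at least 4.86 and 4.70 log2 units above young WT. The sex-linked list had a median of -4.34 over 4 counted genes for old WT over young WT and -3.95 over 4 for old p16-/- over young WT. Age and sex-linked expression therefore differ together in the comparisons with young WT, whereas Xist was at -0.16 between the old arrays.

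The comparison of old WT with young WT asks how donor age bears on reprogramming intermediates. Interferon response genes stood highest among the lists on the old WT array, with a median of 1.17 over 30 genes (2.25-fold), and 19 were at least 2-fold higher. Macrophage and leukocyte genes stood lowest after the sex-linked list, with a median of -2.01 over 21 genes (4.02-fold), and 19 were at least 2-fold lower. Cell cycle genes were lower by a small and even amount, with a median of -0.31 over 39 genes, 38 of them below 0. In all, 425 of 14546 counted genes were at least 2-fold higher and 461 at least 2-fold lower. With a signal of at least 1000 on the brighter array, 102 of 8717 were higher and 49 lower, and 429 of the 886 genes in the first pair of counts rest on a bound.

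In the interferon list, the ubiquitin-like modifier Isg15 was at 2.28, Ifi44 at 2.22, the chaperone-like Rtp4 at 2.00 and the antiviral Oasl2 at 1.86. Members that were not 2-fold apart included Rsad2 at -0.65 and the chemokine Cxcl10 at -0.43. The list's median exceeded that of all 10000 random lists (percentile 100). Antigen presentation genes were also higher (median 0.43 over 18 genes, percentile 100), with the immunoproteasome subunit Psmb8 at 1.14 and the class II gene H2-Ab1 at 1.92.

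In the macrophage and leukocyte list, the macrophage marker Adgre1 (F4/80) was at -2.83, Ms4a7 at -2.45, Cd52 at -2.40 and the complement gene C1qc at -2.35. The lysozyme genes Lyz1 and Lyz2 were at -2.09 and -2.20. Itgam and Cd14 were the members within 2-fold, at -0.01 and 0.09. The list lay at percentile 0 of the random lists. The adaptor gene Tyrobp, a member, was at -2.32. Lilrb4a at -2.66 and Clec4d at -2.47, both outside the list, were also among the 12 lowest ratios at a signal of at least 1000.

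The proliferation marker Mki67 was at -0.49, the cyclin gene Ccnb2 at -0.47 and the DNA replication genes Mcm3 and Top2a at -0.41 and -0.37. No cell cycle gene was 2-fold apart, and the thymidylate synthase gene Tyms alone lay above 0, at 0.92. The list stood at percentile 0.

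Among genes above background on both arrays with an ordinary symbol, Igfbp5, an insulin-like growth factor binding protein, had the highest ratio at 3.28, with signals of 1252 on young WT and 11658 on old WT. The collagen-binding integrin subunit Itga11 was at 2.87, the transcription factor Tbx1 at 2.46, the Wnt inhibitors Wif1 and Dkk3 at 2.94 (signal of 594 on old WT) and 2.13, the thyroid hormone deiodinase Dio3 at 2.29, the cartilage link protein Hapln1 at 2.21 and the lysophospholipase Enpp2 at 2.13. The receptor genes Klra7, Klra16 and Klra4 were at 2.35, 2.22 and 2.13, and the other probes of Klra7 were not well above background on any array. At the lower end stood the matrix glycoprotein Thbs4 at -3.06, the sphingomyelinase Smpd3 at -2.71 and Syt10 at -2.27.

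Secretory genes linked to senescence had a median of 0.25 over 36 genes (percentile 100), with 6 at least 2-fold higher, among them Igfbp5, Mmp13 at 1.59 and Mmp2 at 1.58, and 1 lower. Wnt pathway genes had a median of 0.30 over 24, with 4 higher, including Ccn5 at 1.68. TGF-beta response genes had a median of 0.16 over 25, with 14 above 0 and 11 below. Bmp4 was at 2.10 (another probe was not well above background on any array) and Ltbp2 at 1.24, whereas Tgfbi was at -0.48 and Id2 at -0.43. Fibroblast and mesenchymal genes had a median of 0.15 over 36 genes, none of them 2-fold apart, and Col1a1 was at -0.05. Cartilage and bone genes had a median of 0.48 over 11, with Comp at 1.44. Schwann cell and melanocyte genes had 0.87 over 8, with S100b at 1.20 and Ngfr at 1.01. All of these lists stood apart on the higher side.

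Further lists that stood apart on the higher side were smooth muscle and pericyte genes (0.21 over 14), posterior Hox genes (0.25 over 14) and antioxidant and glutathione genes (0.06 over 33, with Gpx3 at 2.05, Sod3 at 1.17 and Mgst1 at -1.06). On the lower side were immediate early and heat shock genes (-0.15 over 19), keratinocyte genes (-0.25 over 17, with Krtdap at -1.12) and adipocyte genes (-0.26 over 9). Apart from the adipocyte list, each of these lost its place under an alternative. This was the mean of members for smooth muscle, posterior Hox (percentile 95.1) and immediate early genes (7.91; also 3.69 at a signal of at least 1000), unmatched random lists for antioxidant genes, and no background filter for keratinocyte genes (2.64). Pluripotency genes (0.09 over 24), epithelial genes (0.09 over 19), cyclin-dependent kinase inhibitors (0.00 over 7), p53 targets (0.02 over 26), glycolysis (-0.01 over 22), oxidative phosphorylation (-0.05 over 32), endothelial (0.00 over 9), skeletal muscle (0.15 over 13) and housekeeping genes (-0.05 over 15) did not stand apart. Nanog was at -0.22.

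The other genes that the naming rule takes from this comparison had signals under 1000 on both WT arrays, where single spots of dim probes can read high. Higher ones were Spata31d1a (3.27), Cypt4 (3.06), Chrnb4 (2.79), Rab11fip4os1 (2.68), Clec2h (2.60), Aspg (2.55), Dll3 (2.47) and Mymk (2.39), and lower ones were Padi2 (-3.61), Irgc1 (-3.61), Nxpe5 (-3.58), Smtnl1 (-3.46), Cbln2 (-3.38), Gimap4 (-3.17), Six2 (-2.98), Hcrtr1 (-2.85), Cd300c2 (-2.81) and Pirb (-2.78). The largest bounds besides the sex-linked genes were Galnt13 (3.95), Foxr1 (3.62), Adam26a (3.55) and Olfr571 (3.44), and Cfap58 (-4.44), Olfr1100 (-4.09) and Pou4f3 (-4.00). A second probe of Dll3 gave 0.32 and a second probe of Hcrtr1 gave -0.03. Other probes of Padi2 and Gimap4 were not well above background on both WT arrays. Dll3 on young WT and Gimap4 on old WT were above background by another probe only, and by the brightest probe alone their values are bounds (2.47 and -3.0). List members that the rule takes but that are not named above include Eda2r, at 1.29 with 0.06 by a second probe.

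**Figure D1:**
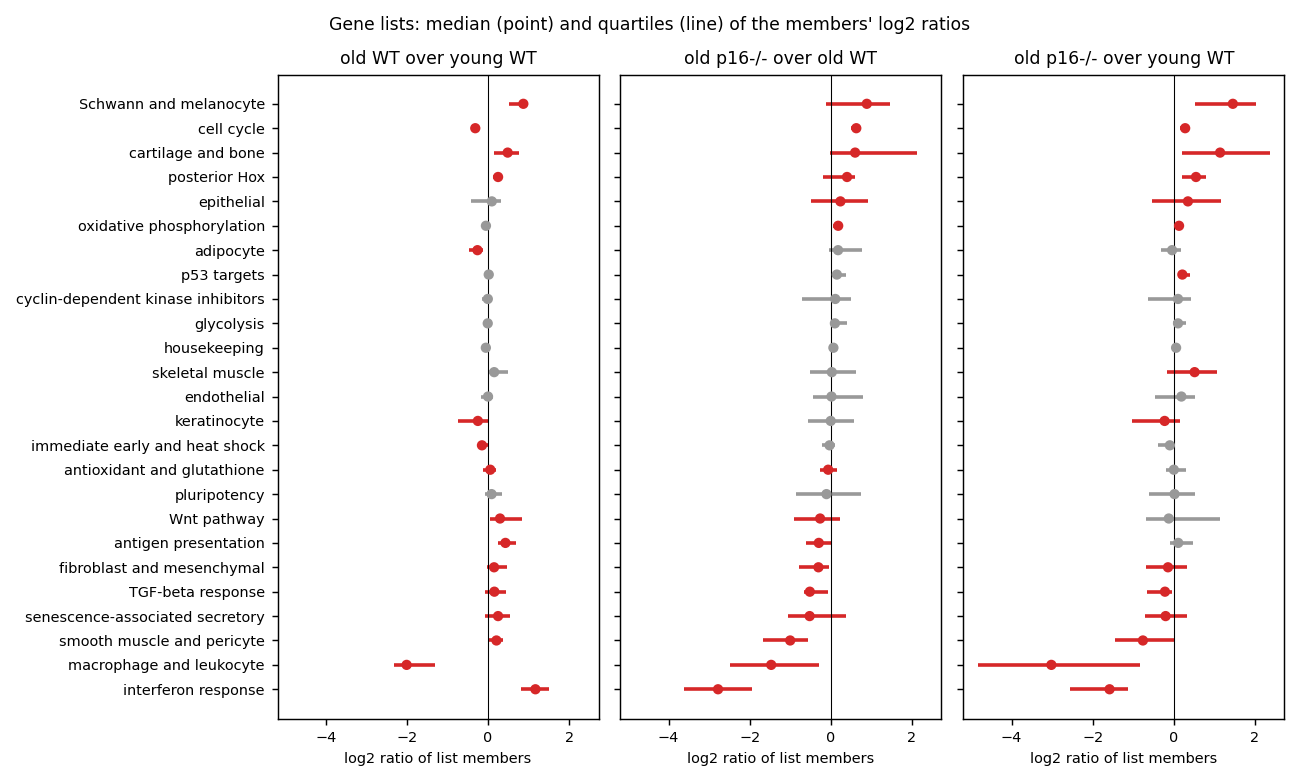
Median (points) and quartiles (lines) of the log2 ratios of the members of each gene list in the 3 comparisons, with 1 array per group. The reprogramming factors and the sex-linked list are not drawn. Red marks lists in the outer 5% of matched random lists and grey the others. Interferon response genes lay at 1.17, -2.78 and -1.59 and macrophage and leukocyte genes at -2.01, -1.47 and -3.02, from left to right.

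The comparison of old p16-/- with old WT asks how loss of p16 bears on old cells. Interferon response genes were lower on the p16-/- array, with a median of -2.78 over 30 genes (6.88-fold), and 29 were at least 2-fold lower. Cell cycle genes were higher by a small and even amount, with a median of 0.62 over 40 genes, 39 of them above 0. Macrophage and leukocyte genes were lower still than on old WT, with a median of -1.47 over 20 genes, 12 of them at least 2-fold lower; 10 of the 20 values are bounds, and at a signal of at least 1000 the median was -0.74 over 5 genes, with 2 lower. Smooth muscle and pericyte genes had a median of -1.0 over 14, with 7 at least 2-fold lower, 3 of these by bounds. In all, 865 of 14691 counted genes were at least 2-fold higher and 971 lower (12.5%, against 6.09% for old WT and young WT). With a signal of at least 1000, 236 of 8835 were higher and 372 lower (6.88%, against 1.73%).

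The interferon genes with the largest ratios were Ifi27l2a at -4.69, the deconjugating protease Usp18 at -4.46, Oasl2 at -4.39 and Ifit3 at -4.07. The transcription factor Irf7 was at -3.51 and Ifi35, the member within 2-fold, at -0.82. The list lay at percentile 0. Antigen presentation genes were lower (-0.30 over 18, percentile 0.280), with Nlrc5, an activator of class I genes, at -2.44 (another probe was not well above background) and Psmb8 at -1.74. At a signal of at least 1000 that list did not stand apart (-0.07 over 11, percentile 10).

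Within the macrophage and leukocyte list, Lyz1 was at -5.00, and the protease gene Ctss, Lyz2 and Tyrobp were not well above background on p16-/- and lower by bounds of -4.96, -3.17 and -2.84. The mannose receptor gene Mrc1 was among 3 members at least 2-fold higher, at 2.22, and all 3 had signals under 1000. The cell cycle list stood at percentile 100. The mitotic checkpoint gene Bub1b, at 1.06, was the member at least 2-fold higher. Ccnb2 was at 0.97, Mcm2 at 0.89, Mki67 at 0.64 and Tyms at -0.75.

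Fibroblast and mesenchymal genes had a median of -0.31 over 36 (percentile 0), with 7 at least 2-fold lower and 2 higher. The surface marker Thy1 was at -3.99, with signals of 52045 on old WT and 3287 on p16-/-. The actin gene Acta2 was at -1.98, Mfap5 at -1.85, Cnn1 at -1.79 and Tagln at -1.75. Pdgfra and Fap were higher, at 1.60 and 1.5. The collagen genes Col1a1 and Col1a2 were at -0.30 and -0.05 and the intermediate filament gene Vim at -0.03. TGF-beta response genes had a median of -0.52 over 25, with 4 lower, among them Ankrd1 at -2.66, Tgfb3 at -2.11 and Ltbp2 at -1.37.

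Secretory genes linked to senescence went both ways, with 10 of 36 at least 2-fold lower and 6 higher (median -0.53, percentile 0). Igfbp2 and Igfbp4 were at -2.39 and -2.29, and the collagenase gene Mmp13 was at 2.96. Wnt pathway genes had a median of -0.27 over 24, with Wnt5a at -2.0 and 6 at least 2-fold lower, and did not stand apart by the mean of members (percentile 2.97). Cartilage and bone genes had a median of 0.60 over 15 with 5 higher, including the cartilage collagens Col2a1 at 3.26 and Col10a1 at 1.92, whereas Comp was at -1.53. Schwann cell and melanocyte genes had 0.88 over 11, with S100b at 2.11, Ngfr at 1.43 and the myelin gene Mbp at -1.13. Epithelial genes had 0.23 over 21, with the keratin genes Krt18 and Krt8 at 2.10 and 1.80. The epithelial list did not stand apart with a filter on both arrays (percentile 95.8), at a signal of at least 1000 (96.5) or by the mean (87.9).

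Among genes above background on both arrays, the highest ratio was that of the serine protease inhibitor Serpina3f at 7.92 (signals of 165 and 40130), and also higher were Iapp (6.13), Serpina3i (5.78), the alpha-globin genes Hba-a1 and Hba-a2 (5.52 and 5.06), the transglutaminase subunit F13a1 (5.32), Cst13 (4.95), Serpina3n (4.81) and the chitinase-like Chil1 (4.44). A second probe of Serpina3i gave 1.16, and a second probe of F13a1 was not well above background. Pcdh15 (5.05), Zfp879 (4.71) and Marchf10 (5.03) had signals under 1000, a second probe of Marchf10 gave -0.36, and other probes of Pcdh15 and Zfp879 were not well above background on p16-/-. On old WT these 3 genes were above background by another probe only, and by the brightest probe alone their values are bounds of 2.94, 3.49 and 4.75 for Pcdh15, Zfp879 and Marchf10. By bounds, Ifi202b was higher by at least 8.41, with a signal of 12176 on p16-/-, and H60b (6.89), Ifi214 (5.95), Gdpd3 (5.27) and Scrg1 (5.25) followed. Lower were the transcription factor Zic1 (-5.80), Ifi27l2b (-4.43), the gamma-secretase subunit Aph1b (-4.32), Myoc (-3.86) and the membrane glycoprotein Pdpn (-3.69, signals of 88662 and 6874; -3.08 by a second probe). The values of Zic1 and Aph1b rest on 1 probe each: second probes, well above background on all arrays, gave -0.91 and -0.49. A second probe of Ifi27l2b was not well above background. Ifi211 (-7.35), Trim12a (-7.05), Acyp2 (-5.46) and Gcnt1 (-5.04) were lower by bounds.

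Oxidative phosphorylation genes (0.18 over 32, none 2-fold apart) and posterior Hox genes (0.40 over 15, with Hoxb13 at -1.26, Hoxc13 at -1.23 and Hoxd8 at 2.91) stood apart on the higher side, the latter not by the mean of members (percentile 92.6). Hoxd8 had signals under 1000 on both old arrays. Antioxidant and glutathione genes (-0.07 over 34, with Gsta2 at 1.75) stood apart on the lower side, although not under 5 of the alternatives, with percentiles from 3.92 with cyclic loess to 22.4 with the mean of members. Pluripotency genes (-0.11 over 24) did not stand apart: 4 were at least 2-fold higher, with Tfcp2l1 at 2.18, and 5 lower, with Fgf4 at -1.93. Nanog was at -0.15. The reprogramming factors (-0.35 over 3), cyclin-dependent kinase inhibitors (0.11 over 7), p53 targets (0.15 over 26, with Perp at 1.39), glycolysis (0.10 over 22, with Aldoc at 1.06), immediate early and heat shock (-0.03 over 19), keratinocyte (-0.01 over 18), endothelial (0.01 over 10), skeletal muscle (0.02 over 14, with Acta1 at -2.18), adipocyte (0.18 over 10, with Lpl at 2.78) and housekeeping genes (0.06 over 15) did not stand apart either. Among the kinase inhibitors, Cdkn1a (p21) was at 0.11 and Cdkn1c (p57) at 1.18.

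Old p16-/- was also set against young WT. Macrophage and leukocyte genes had a median of -3.02 over 22 genes (8.11-fold), with 16 at least 2-fold lower, and interferon response genes had -1.59 over 29, with 23 lower. Cell cycle genes had a median of 0.28 over 40, none of them 2-fold apart. Cartilage and bone genes had 1.14 over 13, with 7 at least 2-fold higher, and Schwann cell and melanocyte genes 1.45 over 9, with 5 higher. In all, 906 of 14281 counted genes were higher and 994 lower (13.3%), and 303 and 372 of 8871 (7.61%) at a signal of at least 1000.

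Among genes above background on both arrays with an ordinary symbol and a signal of at least 1000, the highest ratios were those of Serpina3f (8.68), Hba-a2 (5.47), the membrane glycoprotein Cd200 (4.99), Serpina3n (4.94), the deiodinase Dio2 (4.93), Mmp13 (4.55), Stac (4.35), Col2a1 (4.08), Serpina3b (3.95) and Tbx1 (3.87). The lowest were Lyz1 (-7.09), Zic1 (-5.73), Thbs4 (-5.18), Tshz2 (-4.58), Thy1 (-4.35), Smpd3 (-4.25), Aph1b (-4.19), the Fc receptor chain Fcer1g (-4.08), Ifi27l2b (-3.98) and the retinaldehyde dehydrogenase Aldh1a3 (-3.97). Adamts12 (4.09), Marchf10 (6.39), Tesmin (-3.85) and Ccl6 (-3.83) had signals under 1000. Second probes gave -0.43 for Zic1, -0.42 for Aph1b and -0.16 for Marchf10, all well above background on every array. Those of Adamts12 (-0.56, not well above background on p16-/-) and Tesmin (0.94, not well above background on young WT) lay in the other direction. The values of Adamts12, Marchf10 and Tesmin use the background call of another probe on 1 array, and by the brightest probe alone they are bounds of 3.32, 4.18 and -2.73. Among interferon genes, Ifi27l2a was at -3.73 and Cxcl10 at -3.16, whereas Gbp2 was at 0.02. S100b was at 3.31, Ngfr at 2.44, Hapln1 at 2.98, Pdgfra at 2.10 and Fap at 1.95.

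Also apart on the higher side were epithelial (0.35 over 20), oxidative phosphorylation (0.13 over 32), posterior Hox (0.54 over 14), p53 target (0.21 over 26) and skeletal muscle genes (0.51 over 12). The skeletal muscle list lost its place under 7 alternatives (percentile 90.3 with the mean of all probes), the epithelial list with a filter on both arrays (0.15, percentile 90.2) and with the mean (77.8), and oxidative phosphorylation with unmatched lists (95.4). On the lower side were fibroblast and mesenchymal (-0.15 over 36), TGF-beta response (-0.22 over 25), smooth muscle and pericyte (-0.76 over 13), keratinocyte (-0.23 over 18) and senescence-linked secretory genes (-0.20 over 35), of which 7 were at least 2-fold higher and 6 lower. The mean of the secretory genes was 0.076, opposite in sign to the median (percentile 75.8). The keratinocyte list lost its place at a signal of at least 1000 (4.05) and with the mean (10.1). Pluripotency (0.02 over 23), the reprogramming factors (-0.04 over 3), cyclin-dependent kinase inhibitors (0.10 over 7), antigen presentation (0.11 over 17), Wnt pathway (-0.13 over 23), antioxidant and glutathione (0.00 over 34), glycolysis (0.10 over 22), immediate early and heat shock (-0.10 over 19), endothelial (0.18 over 8), adipocyte (-0.04 over 10) and housekeeping genes (0.05 over 15) did not stand apart.

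The 3 arrays also allow a count of genes that differed between old WT and young WT and in the opposite direction between old p16-/- and old WT. Of the interferon list, 19 members were at least 2-fold higher on old WT than young WT and at least 2-fold lower on p16-/- than old WT, 17 of them among the 55 such genes with a signal of at least 1000. Without that threshold 264 genes met this condition, and 51 genes were lower on old WT and higher on p16-/-. Of the latter, 3 had a signal of at least 1000 in both comparisons: Syt10 (-2.27, then 3.43) and, named after their values were seen, the prostacyclin synthase gene Ptgis (-1.83, then 1.11) and Wdfy1 (-1.78, then 1.42). The rule also names Elavl2, Padi2, Zfp963, Inpp5d, Kcnj10, Trpv3, Ms4a6b, Btnl5-ps and Olfr985, each with WT signals under 1000. The genes named at the other end, Galnt13, Adam26a, Olfr571, Trcg1, Apol10a, Mro, Olfr1424, Vmn1r10, Abcc6 and Olfr411, were above background on old WT alone, at signals from 508 to 824.

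Both comparisons share the old WT array, whose own deviations enter them with opposite signs. Across 12887 genes above background on all arrays, which are not independent replicates, the ratios correlated at -0.22 (covariance -0.051), and 97 genes were higher and then lower and 25 lower and then higher. When the 3 values of each gene were permuted 1000 times, the mean correlation was -0.50 (covariance -0.157) and the mean counts were 179 ± 11.0 and 183 ± 11.2 (SD over permutations). The opposite changes were thus fewer than 3 exchangeable arrays give. Permutation spreads each array's deviations over all 3, so these means depend on how far the other arrays deviate. They do not show how many opposite changes would arise without an effect. The array that lay at least 2-fold from both others most often was p16-/- (775 genes), followed by young WT (188) and old WT (122).

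**Figure D2:**
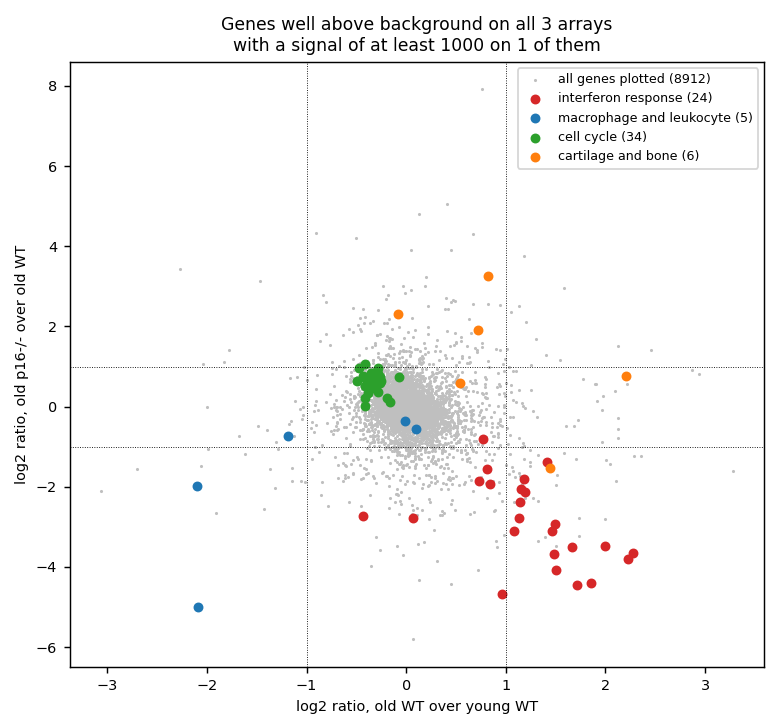
Log2 ratio of old p16-/- over old WT (vertical axis) against that of old WT over young WT (horizontal axis) for 8912 genes, 1 point per gene and 1 array per group, with members of 4 gene lists in colour and dotted lines at 2-fold. Isg15 at 2.28 and -3.65 and Ifi44 at 2.22 and -3.81 lie at the lower right, and Lyz1 at -2.09 and -5.00 at the lower left.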

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

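All but 3 of the tests in this part were chosen only after the result was seen. Those on genes near Cdkn2a, on single probes and on array noise were written before. Probes without a gene name, which no comparison above uses, also differed between arrays. Of those counted, 231 were at least 2-fold higher on old WT than on young WT, 424 on old p16-/- than on old WT, and 387 on old p16-/- than on young WT. They were singled out because they carry signal outside the named genes; 242, 392 and 377 were lower.

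Interferon response genes were higher on old WT than on both other arrays. For leukocytes in the old WT culture, the macrophage and leukocyte list was lower there than on young WT (median log2 ratio -2.01). This argues against the kinds that the list covers, mainly macrophages. Other leukocytes stay open, since the list does not cover them. Outside it, Klra7, Klra16, Klra4 and H2-Ab1 were higher on old WT, and Lilrb4a and Clec4d were lower. Scaling between arrays is argued against by an interferon list median of at least 1.104 under every scaling tried. Donor age alone, and donor sex alone, are argued against as the source of the whole pattern by the old p16-/- array. It shares its age and Xist signal with old WT, and the interferon list lay below young WT there (-1.59). Either could still account for the rise of old WT over young WT, where age and sex-linked expression differ together. Loss of p16, a different genetic background of the p16-/- donors and an interferon stimulus in a single culture remain open and untested, since each is tied to a single array per group.

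More genes were at least 2-fold apart between old p16-/- and old WT than between old WT and young WT. For a chromosome segment carried along with the Cdkn2a mutation, 19.0% of the 100 detected genes nearest Cdkn2a were apart. This was at percentile 88.7 of all such windows (median 12%, 95th percentile 21%). The window itself holds few of the genes apart, 19 against 1836. The length of a carried segment is not known and longer windows were not examined, so this does not decide how much such a segment contributes. Sequence variants under single probes stay possible, as for Zic1 and Aph1b. Among 189 2-fold genes with 2 probes above background on all arrays, the other probe differed by less than 25% for 13.2% (95% Wilson interval 9.12 to 18.8). Between the WT arrays this was 26.2% of 42 genes (15.3 to 41.1). The share was thus not higher, but the intervals overlap and probes without signal on 1 array are left out. This cannot decide whether variants add to the excess. A ratio of replicate-spot SDs of 0.955 (old p16-/- over old WT) argues against more spot-to-spot noise, but cannot show differences in RNA, labelling or hybridization. A different genetic background of the p16-/- donors may contribute: Ifi202b, known to differ between inbred strains, was higher by at least 8.41, but background and genotype cannot be told apart with 1 array per genotype and no strain in the labels. Loss of p16 itself and separate donors stay open as well.

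Genes above background on 1 of 2 arrays supply much of the counts. Single-spot artefacts are a candidate explanation: at the rate seen in replicate spots of dim probes, where 61 of 1250 gave a 2-fold call, 306 genes are expected among the 429 called by a bound between old WT and young WT. The corresponding numbers are 268 of 618 for old p16-/- over old WT and 332 of 690 for old p16-/- over young WT. The estimate assumes that probes spotted once behave like those spotted 10 times. Its rate includes spots marked as outliers, which the counts leave out, so it may be too high. Genes with a signal of at least 1000 are outside the range in which such spots were seen (1 of 1790 bright replicate-spot ratios of old p16-/- over young WT was off by 2-fold), and for the other bounds no biological explanation was tested.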

How the results depend on the processing

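The values for a signal of at least 1000, those without genes of the X and Y chromosomes and those with the background call of the brightest probe come from alternatives chosen only after the data were seen; the others were planned. No paired analysis was possible because the result comes from no test and each group has 1 array, and leaving out a replicate was not possible for the same reason. Median centring, quantile normalization, cyclic loess, the mean of all probes, the deposited series values, outlier spots kept, the background call of the brightest probe and removal of X and Y genes moved no gene count by more than 1.5 times. Counts below are given for old WT over young WT, old p16-/- over old WT, and old p16-/- over young WT, in that order. With normexp, 256, 563 and 603 genes were higher, 266 were lower in the first comparison, and 18 were lower on old WT and higher on p16-/-. With a filter on both arrays, 237, 551 and 562 were higher, 220 and 648 were lower in the first and last, 25 and 97 went in opposite directions (lower then higher, and the reverse), and the correlation of the ratios was -0.22. Without a filter, 905, 1300 and 1439 were higher, 788, 1619 and 1508 lower, and 160 and 555 opposite, with a correlation of -0.39. At 3-fold, 196, 445 and 452 were higher, 255, 463 and 497 lower, and 13 and 139 opposite. At a signal of at least 1000, 102, 236 and 303 were higher, 49, 372 and 372 lower, and 3 and 55 opposite. Filters and sizes move counts by construction, since they change which genes are counted; for normexp the cause was not tested. The order of the comparisons, fewest genes for old WT over young WT, held in each of these.

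Between 12 and 18 lists stood apart under every alternative, against 17, 15 and 16. In all, 15 of these calls were lost under some alternative, 30 times in total, and each is given beside its list above; the interferon, macrophage and leukocyte, and cell cycle calls were not among them. Signs reversed for the senescence-linked secretory list over young WT with the mean of members (0.076), the skeletal muscle list over young WT without a filter (-0.073), Marchf10 under quantile normalization (-0.27 over old WT and -0.15 over young WT), where another probe became the brightest, and Padi2 over young WT with the mean of all probes (0.38). For the lists and Padi2 the cause was not tested. Of named genes at least 2-fold apart, 73 of 83, 87 of 101 and 86 of 99 stayed so under every scaling. Signal over background limits all values of dim probes, for which only bounds can be given.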

Other observations

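No test in this part was planned; the values were picked after they were seen and are given without explanation. The serine protease inhibitors Serpina3f, Serpina3i and Serpina3n were 7.92, 5.78 and 4.81 log2 units above old WT on the p16-/- array, although a second probe of Serpina3i gave 1.16, and the alpha-globin genes Hba-a1 and Hba-a2 were 5.52 and 5.06 above. Within the Ifi200 family, whose members bind nucleic acids, Ifi202b and Ifi214 were higher by bounds of 8.41 and 5.95, and Ifi211 was lower by a bound of -7.35.

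Zic1 had signals of 3754 on young WT, 3777 on old WT and 68 on p16-/-, whereas a second probe, well above background on all arrays, gave -0.91 for p16-/- over old WT and -0.43 over young WT. Of the posterior Hox genes, Hoxb13 and Hoxc13 were lower on p16-/- than old WT (-1.26 and -1.23), Hoxd8 was higher (2.91, with signals under 1000), and Hoxa9 and Hoxc11 were at 0.57 and 0.61. Tbx1 had signals of 286, 1511 and 4015 on young WT, old WT and p16-/-.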
